A study of Mus musculus with 18 samples.

How the data were processed

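Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in mouse CD4 T cells grown from naive cells under Th1-polarising conditions. The 18 samples form 6 groups of 3, by genotype (Id3 knockout, Id3-KO, or wild type, WT), the submitters' cell label (Th1, Tcmp or Teff; the last pair of labels is used as given, since the labels do not spell them out) and time (24 h for Th1, 72 h for Tcmp and Teff). Whether the 3 samples of a group came from separate animals or cultures is not given in the sources used here.

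Trim Galore, BWA, Picard and edgeR, and the genome build GRCm39, are named in the submitters' processing notes without versions, roles or order. The file analysed is a table of the authors' own comparisons with 395898 rows, 65983 regions under each of 6 contrasts, and holds no value for a single sample. Per the file headers, each region carries a deposited log2 fold change of a representative window, a p-value, an adjusted p-value, the number of windows in the region, the number of windows counted as up or down, and the genes it overlaps or lies near. The regions hold 409588 windows in all, a median of 6 per region (range 1 to 16), and are 300 to 1100 bp wide. Regions with a single window are 300 bp wide and all widths are multiples of 50 bp. The other deposited columns, of window numbers and region width, have no unit beyond the count of windows and bp. How the log2 fold changes were normalized, and which software merged the windows, are not given in the sources used here. Library depth is unknown from this table, so no interval that needs read counts is given, and none of the deposited values has an SD or an n. Benjamini-Hochberg adjustment of the deposited p-values within each contrast returned the deposited adjusted p-values.

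Each contrast was read as the group named first over the group named second, as its name gives it. The names of the 72 h knockout contrasts do not say which WT samples were used. The mean log2 fold change of the Teff contrast minus that of the Tcmp contrast was -0.39, and the Id3-KO Teff against Tcmp contrast minus the WT one was -0.40, while the Id3-KO contrast alone had -0.81. The values therefore add up only if each knockout group was compared with WT samples of its own cell label. The pooled 72 h contrast had a mean of 0.38, as did the mean of the Tcmp and Teff contrasts.

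Before any comparison was made, the table was checked for a relation between its statistics and its row order. In all 6 contrasts the p-value of the best window of a region (the region p divided by its number of windows, visible where the region p is below 1) never fell from the first region of chromosome 1 to the end of the table. The deposited statistics were for this reason not read as belonging to the region or gene in their row. They were used as a set for each contrast. The best window of a region was its first window throughout. If all windows were sorted by p-value, its running number is also the rank of its p-value among all windows. The 65983 listed windows are then a spread-out sample, by rank, of the 409588. All counts of windows past a threshold rest on this reading, which was not shown directly. The number of windows past an adjusted p of 0.05 is the largest such rank at which the Benjamini-Hochberg criterion held. Directions and log2 fold changes were counted over the listed windows up to that rank, with 95% Wilson intervals that cover counting error only. Overlapping windows share reads, so windows are not independent and these intervals are too narrow. Where the region p was 1, the window p was interpolated from neighbouring ranks.

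Windows were also matched between the Tcmp, Teff and pooled 72 h contrasts without using positions. The pooled log2 fold change of a window is the mean of its values in the other 2, and the table prints about 15 digits, so triples that satisfied this relation within 2e-14 were taken as the same window. This gave 1820 matches, against a mean of 2 (at most 5) in 5 searches with a deliberately offset target. After matches that shared a value were removed, 1802 windows were left. Both the matching and the recovery of window counts and directions from ranks were tried on simulated data of known content. The latter used the real numbers of windows per region. The outcomes of these trials are not given here. The simulated lists for matching were shorter than the real ones and kept a larger share of windows. In the other simulation all windows had the same spread and independent noise. It could therefore not test the centring described below where spreads differ.

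The design fixed before the data were examined called for the authors' adjusted p at 0.05 where only comparisons were given, and those region counts are reported. It also called for tests of gene lists, of overlaps between contrasts and of promoter shares, for named genes chosen by their region's values, and for motif counts. Calls of list genes and shared calls were counted to examine the order of the table, and are not given as results about genes. No list test or promoter test was run, because each needs statistics that belong to their regions. The rule for named genes (Id3, the largest changes at regions of high accessibility, the smallest p-values of each list and a set of T cell genes) could be applied only to Id3. The other genes named below were chosen after their values had been seen, to show the order of the table. Motifs and GC content need a genome sequence, which was not used here. Differences of the knockout effect between cell labels have no deposited test. The use of ranks, the matching across contrasts and the centring on the median were chosen after the table had been seen. Alternatives were an adjusted p of 0.01, an absolute log2 fold change of at least 1, and the median log2 fold change subtracted with the standard error rebuilt from the fold change and its p, by a normal or a t distribution with 12 degrees of freedom. Computations used Python 3.11.15 with numpy 2.4.6, numba 0.67.0, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.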

Results

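Accessibility was compared between Id3-KO and WT CD4 T cells at 24 h (Th1) and 72 h (Tcmp and Teff), and between Teff and Tcmp cells of each genotype at 72 h. Id3 is an inhibitor of E proteins, a family of basic helix-loop-helix transcription factors that direct lymphocyte development. Each of the 6 groups had 3 samples. The data were the authors' deposited table of 65983 regions in 6 contrasts, with no value per sample, so every fold change below is the authors' value and has no replicate error.

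In every contrast the statistics followed the order of the regions along the genome. The p-value of the best window never fell between successive regions with a visible window p, from chromosome 1 through chromosomes 10 to 19, 2 to 9, X and Y, and the best window was the first window of its region in 65983 of 65983 regions. Unrelated windows would give a share of about 21.2%. Regions past an adjusted p of 0.05 therefore ended at a point in the table that differed between contrasts, at the latest in row 39878 of 65983, on chromosome 3, in the Id3-KO Teff against Tcmp contrast. In the Th1 contrast the last of the 8368 called regions was on chromosome 12 (85616951 to 85617250, GRCm39), and 100% of the regions of chromosome 1 were called. In the WT Teff against Tcmp contrast all 1534 calls lay on chromosome 1. None of the regions on chromosome X was called in any of the 6 contrasts.

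**Figure D1:**
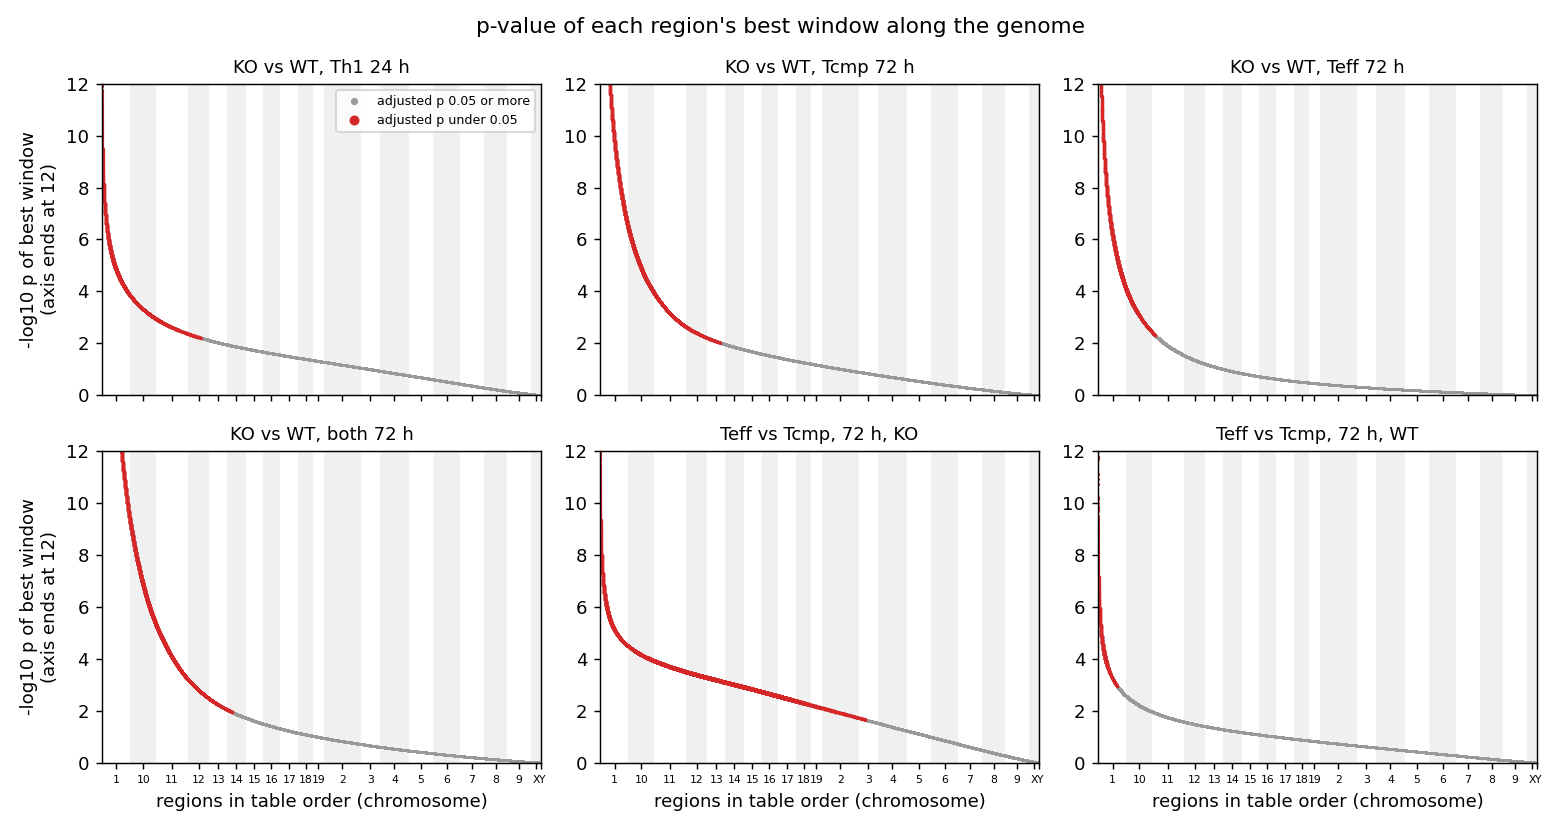
The −log10 p-value of each region's best window (vertical axis, ending at 12) against the region's place in the table (horizontal axis, chromosomes shaded in turn) in the 6 contrasts. Red points are regions past the deposited adjusted p of 0.05. Where it is visible, in 25375 to 53444 of the 65983 regions by contrast, the p-value never falls from left to right. Elsewhere it was interpolated from neighbouring ranks. All 1534 called regions of the WT Teff against Tcmp contrast lie on chromosome 1.

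The values listed at T cell genes followed the same order. The region at the promoter and an exon of Sox17, a transcription factor of endoderm and endothelium, is the first in the table (chromosome 1, 4566451 to 4567050, GRCm39). In the authors' deposited table it had the lowest adjusted p-value of the Th1 contrast, with a log2 fold change of -3.93, and also of the Tcmp contrast, with 5.98, and of the Teff contrast, with -7.12. Of 290 genes in lists of T cell programmes and other cell types fixed before the data were examined, 258 overlapped a region. In the Th1 contrast 46 of them had a called region, and these lay on chromosomes 1, 10 and 11. They included all 28 list genes on chromosome 1, among them Ctla4, Pdcd1, Icos, Cd28, Stat4, Il18r1 and Bcl2, which span inhibitory receptors, costimulation, Th1 signalling and survival. Genes on chromosomes late in the table, such as Cxcr5 (chromosome 9), a homing receptor of follicular helper cells, had no call in any contrast.

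Because of this order the deposited values at these genes are not reported as changes of the genes. The same limit holds for the targeted gene. At Id3 (chromosome 4) the table lists a promoter region (135867501 to 135868100), a region over the promoter and an exon (135870851 to 135871350) and a region downstream (135874851 to 135875600). Their listed log2 fold changes in the Th1 contrast were -0.47, -0.68 and 0.51 in the authors' deposited table, none past the threshold. These values could not check the genotype labels or the sign of the contrasts, which was taken from the contrasts' names.

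At 24 h most windows past the threshold were lower in Id3-KO than in WT Th1 cells, as deposited. Of 409588 windows, 136592 (33.3%) were past an adjusted p of 0.05 in the authors' statistics, here ranked over windows. Among the 22169 listed windows up to that rank, 91.2% (95% interval 90.8 to 91.6) were lower in Id3-KO, with a median fold change of 1.92-fold, and 1945 were higher, with a median of 2.29-fold. The median log2 fold change of all listed windows was -0.57 (quartiles -0.80 and -0.26), so that both quartiles lay below 0. After this median was subtracted, 6087 listed windows were past the threshold and 23.1% of them were lower by a normal approximation of the spread, and 43.5% by a t approximation. As deposited by region, 7546 regions were lower and 822 higher. Here and in the other contrasts such region calls are not counts of changed regions, since the statistics were not read as belonging to their regions.

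At 72 h, in Tcmp cells, most deposited differences had the opposite sign. There 130324 windows (31.8%) were past the threshold, and 90.5% (95% interval 90.0 to 90.8) of the 21121 listed ones were higher in Id3-KO, with a median of 2.23-fold. The 2017 listed windows that were lower had a median of 2.27-fold. The median log2 fold change was 0.51 (quartiles 0.19 and 0.82). After the median was subtracted, 11907 listed windows passed and 56.6% were higher (normal approximation, used for centred values unless the other is named). The deposited region calls were 11174 higher and 1183 lower. The opposite majorities at 24 h and 72 h had the signs of the medians of all listed windows, and were not tested apart from a shift of all windows. Windows could not be matched between the 24 h and the 72 h contrasts, so the data do not show whether the windows lower at 24 h were those higher at 72 h. Time and cell label also change together between these contrasts.

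In Teff cells at 72 h fewer windows passed the threshold than in Tcmp cells, and most were also higher in Id3-KO, as deposited. The threshold was passed by 57355 windows (14.0%), and 77.8% (95% interval 76.9 to 78.6) of the 9298 listed ones were higher, with a median of 2.91-fold against 2.37-fold for those lower. The median log2 fold change of all listed windows was 0.07 (quartiles -0.21 and 0.45). Of the 8964 listed windows past the threshold after the median was subtracted, 72.5% were higher. The gap to Tcmp cells was then smaller, with 11907 listed windows there. By the t approximation the counts were 9059 in Teff and 12372 in Tcmp cells. The deposited region calls were 5153 higher and 1131 lower.

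**Figure D2:**
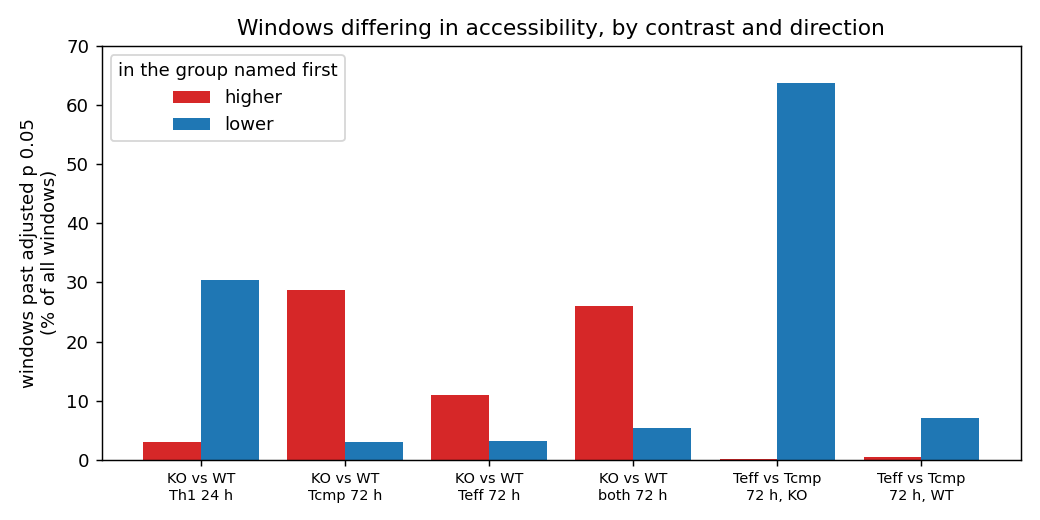
Share of all 409588 windows past an adjusted p of 0.05 (vertical axis, percent) in each of the 6 contrasts, split by direction from the listed windows. Red bars are windows higher and blue bars windows lower in the group named first. Losses lead in the Th1 knockout contrast, in which 33.3% of windows pass, and gains lead in the 3 knockout contrasts at 72 h, all as deposited and without centring.

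The knockout effects in the 2 cell labels at 72 h were correlated. In the 1802 windows matched by their exact fold changes, the log2 fold changes of the Tcmp and Teff contrasts had a Pearson correlation of 0.84 across windows (95% bootstrap interval 0.82 to 0.87, 2000 resamples of windows) and a Spearman correlation of 0.71. Windows are not independent replicates, and the contrasts share no library if each used its own WT group. The sample titles number the Tcmp and Teff samples in parallel, and whether samples of the same number came from the same culture or animal is not given. The expected counts and p-values below take no account of such sharing. They also treat every window as equally likely to pass the threshold. The sign was the same in 1222 matched windows (67.8%, 95% interval 65.6 to 69.9), and in 74.4% after each contrast's median was subtracted. Of the 1802 windows, 551 were past the threshold in Tcmp cells and 257 in Teff cells. Both passed in 225, and 223 of these (99.1%) moved the same way. There were 185 windows higher in both, where independent lists would share 54.7, and 38 lower in both, where they would share 1.74. Fisher's exact test, two-sided, gave p = 3.03e-98 for the higher windows (6.06e-98 adjusted over the 2 tests) and p = 4.03e-51 for the lower (4.03e-51 adjusted), both over windows that share reads. The Tcmp value was the larger one in 83.7% of matched windows, and the Teff value minus the Tcmp value had a median of -0.40 (quartiles -0.65 and -0.14). This difference has no test of its own, and its median is close to the difference of the medians of the 2 contrasts.

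**Figure D3:**
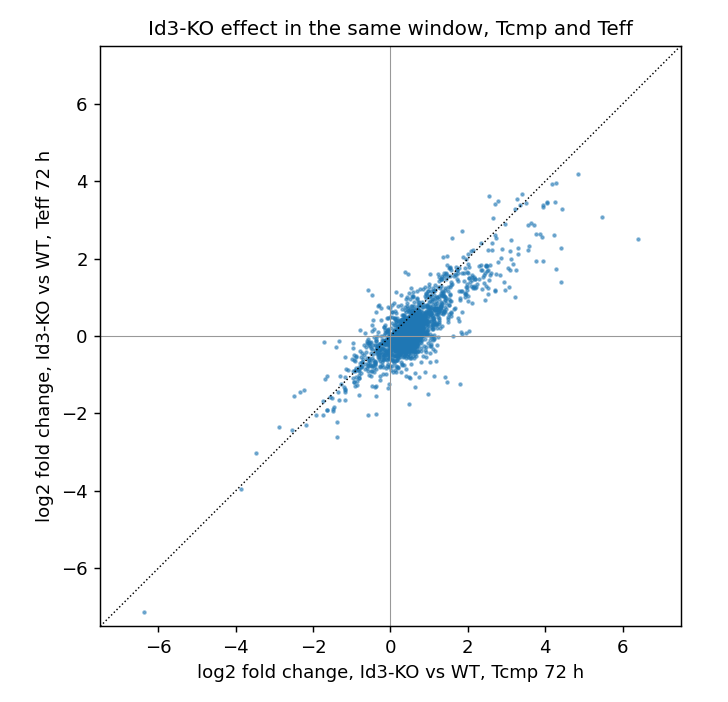
Log2 fold change of Id3-KO against WT at 72 h in Tcmp cells (horizontal axis) and Teff cells (vertical axis), each point 1 of 1802 windows matched by exact fold changes; the dotted line marks equal values. The points follow the diagonal, with a Pearson correlation of 0.84, and 83.7% lie below it.

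The deposited contrast that pooled both labels at 72 h called 15142 regions, 12734 higher and 2408 lower in Id3-KO. By windows, 128563 (31.4%) passed and 82.8% (95% interval 82.3 to 83.3) of the 20835 listed ones were higher. The median log2 fold change was 0.28 (quartiles 0.02 and 0.60). After it was subtracted, 60.2% of the windows that passed were higher.

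Most windows past the threshold were lower in Teff than in Tcmp cells in both genotypes, as deposited. In Id3-KO cells 261368 windows (63.8%) were past the threshold, and 42181 of the 42231 listed ones (99.9%) were lower in Teff cells, with a median of 1.98-fold. In WT cells 30355 windows (7.41%) passed, and 94.7% (95% interval 94.0 to 95.3) of the 4912 listed ones were lower in Teff cells, with a median of 2.10-fold. The median log2 fold change of all listed windows was -0.87 in Id3-KO and -0.44 in WT. After each median was subtracted, 411 listed windows passed in Id3-KO, of which 73.5% were higher in Teff cells, and 645 passed in WT, of which 62.8% were higher. By the t approximation most of the listed windows that passed were lower in Teff cells, 90.1% in Id3-KO and 65.9% in WT. The centred direction thus depended on the approximation. The larger number of windows in Id3-KO was not kept after centring, with 867 in Id3-KO and 898 in WT by the t approximation. The deposited region calls were 29052 lower and 6 higher in Id3-KO, and 1419 lower and 115 higher in WT. Whether the Teff to Tcmp difference itself differed between genotypes has no deposited test.

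**Figure D4:**
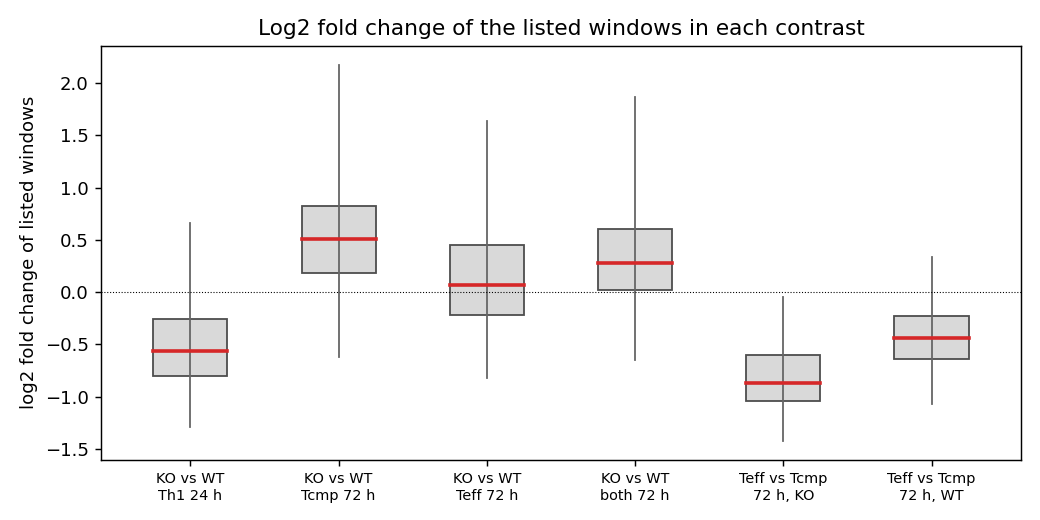
Log2 fold change of the 65983 listed windows (vertical axis) in the 6 contrasts. Boxes span the quartiles, red lines are medians and grey lines reach from the 5th to the 95th percentile. The medians lie between -0.87, in the Id3-KO Teff against Tcmp contrast, and 0.51, in the Tcmp knockout contrast.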

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

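Every setting for results by window, for matched windows and for centred values was chosen after the table had been seen; the adjusted p of 0.01, the minimum fold change and the recomputed adjustment were planned for the region counts. No paired analysis was possible because the table holds no value per sample. For the same reason leaving out a replicate, other splits of the samples, other normalizations, filters on low values, fits to fewer groups, a replicate block and GC correction were not run. The planned settings for gene lists, motifs, the interaction and genomic position were not run either, since those results were not obtained. Library depth is unknown, so its limits were not judged. Recomputing the adjustment changed no count of regions.

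At an adjusted p of 0.01 the deposited region calls fell to 3975 in the Th1 knockout contrast, 14385 in the Id3-KO Teff against Tcmp contrast and 639 in the WT one, and stayed within 1.5 times in the other 3. With an absolute log2 fold change of at least 1, only the Id3-KO Teff against Tcmp count moved by more, to 16986. By listed windows, an adjusted p of 0.01 gave 8524 in Th1, 12461 in Tcmp and 1584 in the WT Teff against Tcmp contrast. The minimum fold change gave 9891 in Th1, 13081 in Tcmp, 10656 in the pooled 72 h contrast, 19628 in the Id3-KO and 3135 in the WT Teff against Tcmp contrast.

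With the median subtracted, by the normal and then the t approximation, the listed windows past the threshold were 6087 and 6571 in Th1, 11907 and 12372 in Tcmp, 411 and 867 in the Id3-KO and 645 and 898 in the WT Teff against Tcmp contrast; the Teff and pooled knockout counts stayed within 1.5 times. The share that was lower became 23.1% and 43.5% in Th1, 43.4% and 34.0% in Tcmp, 27.5% and 26.1% in Teff, 39.8% and 34.4% in the pooled contrast, 26.5% and 90.1% in the Id3-KO Teff against Tcmp contrast, and 37.2% and 65.9% in the WT one. The majority thus changed side in Th1 under both approximations and in the Teff against Tcmp contrasts under the normal one. Subtracting the median places as many of all listed windows above 0 as below it, but does not fix the share among those past the threshold. In the Tcmp, Teff and pooled knockout contrasts the majority lay on the deposited side under both approximations. The Th1 majority depended on the offset of the median. Whether that offset is real is not shown, since a uniform real change is subtracted too. Of the matched windows past an adjusted p of 0.01 in both Tcmp and Teff cells, 155 in number, 100% moved the same way.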

Other observations

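The tests of the table's order and of the window in the last paragraph were chosen after the result had been seen; the tests of a common shift were set before theirs, but the demand that both approximations lead to the same answer was added after their values had been seen.

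The p-values of the table follow the order of the regions along the genome in all 6 contrasts. Real differences between chromosomes do not account for this, since within chromosome 1 the rank correlation of the best-window p-value with position was 1 in the contrast where it was lowest. Sorting of finished regions does not account for it either, since the region p-value fell in many steps and was without a fall in at most 80.5% of them. A candidate explanation is that window results were sorted by p-value before they were joined to window positions, as the best window was then bound to be the first of its region, and it was in 100% of regions in every contrast. The exact fold changes point the same way: of 1802 windows matched across the Tcmp, Teff and pooled contrasts, 0 stood in the same region in all 3, and in the table as it stands the pooled value lies within 0.01 of the mean of the other 2 in only 4.53% of regions.

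If this is the case, gene names read from the table would be those of the first chromosomes in text order and not those of changed regions. Chromosome 1 carries Ctla4, Icos, Cd28, Pdcd1 and Stat4, so a list of called genes may look like a T cell signature with no link to the statistics (best window first in 100% of regions). The correlation of the Tcmp and Teff knockout effects is 0.38 by table row and 0.84 in matched windows. All 8368 regions called in the Th1 contrast are also called in the Tcmp contrast. Calls of both contrasts gather at the start of the table, so this overlap is not read as shared change.

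Most windows past the threshold went one way in 5 of the 6 contrasts by over 80%, and the medians of all windows were off 0 in the same direction. A shift common to all windows, from scaling between libraries or from a uniform change in accessibility, is a candidate explanation. Once the median was subtracted, 23.1% of the Th1 windows that passed were lower by the normal approximation and 43.5% by the t approximation, 43.4% and 34.0% in Tcmp cells, and 26.5% and 90.1% in the Id3-KO Teff against Tcmp contrast. The number of listed windows past the threshold fell from 22169 to 6087 (6571 by the t approximation) in Th1. The number fell from 21121 to 11907 (12372) in Tcmp, and from 42231 to 411 (867) in the Id3-KO Teff against Tcmp contrast. The windows that passed after centring included some that had not passed before it. By the normal approximation, 3347 of the 22169 windows in Th1 and 8758 of the 21121 in Tcmp passed both before and after centring. So did 153 of 42231 in the Id3-KO and 501 of 4912 in the WT Teff against Tcmp contrast. In each of these contrasts most calls thus depended on the offset of the contrast's median. In the Teff knockout contrast 8566 of 9298 passed both times, and in the pooled one 13819 of 20835. The splits do not show the cause of the offset, because subtracting the median removes scaling and a uniform change alike. The bound set beforehand for excluding a shift was under 30% or over 70% lower. It cannot exclude a shift, because a shift can occur together with an excess of gains or losses among the windows. Besides, an excess of gains meets its lower part in contrasts with an excess of losses. In the Id3-KO Teff against Tcmp contrast the normal and t approximations met opposite parts. Scaling and a uniform change both predict such a shift and cannot be told apart here, since the table holds no values per sample.

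Several matched windows were much lower in Id3-KO. The second lowest had log2 fold changes of -3.87 in Tcmp and -3.95 in Teff cells. The lowest one has the smallest p-value of the pooled 72 h contrast. Its log2 fold changes were -6.74 there, -6.36 in Tcmp and -7.12 in Teff cells. It stands in the table's first region in the pooled and Teff contrasts and in its second in the Tcmp contrast. It may lie in the part of Id3 that the knockout removed, which the weaker value of -6.36 does not exclude, but its position is not known from this table. Other listed windows went lower in Tcmp cells, to -8.56, and the lowest listed value in Th1 cells was -4.57. These values do not separate the possible causes, since the same window may not be among those listed in Th1 cells. A strain difference or another lost sequence also stays open. Among listed windows, 48 in Tcmp and 26 in Teff knockout contrasts had log2 fold changes below -3, and 1339 and 498 were above 3. The Th1 knockout contrast had 20 below and 54 above, so its extremes were mostly gains although most windows past the threshold were losses. The counts were 12 and 17 below and 0 and 17 above in the Id3-KO and WT Teff against Tcmp contrasts.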
